A study of Caenorhabditis elegans with 12 samples.

How the data were processed

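Total RNA from adult Caenorhabditis elegans was measured on 12 single-colour microarrays, 1 sample per array. The 4 groups of 3 arrays were N2 worms grown at 15 °C, N2 worms moved to 25 °C for 3 h, N2 worms moved to 25 °C for 12 h, and daf-2(e1370) worms moved to 25 °C for 12 h. Replicates were taken from the sample titles, which carry A, B or 1. The source names call both A and 1 replicate 1 and B replicate 2, which leaves open whether sets A and 1 came from the same worms; the 3 arrays of a group would then be fewer than 3 independent samples. The sources used here give only that the worms were well fed and adult, so neither their exact age nor whether replicates were separate cultures is known.

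Per the labels, total RNA was purified on RNeasy columns and amplified to Cy3-labelled cRNA with the Low Input Quick Amp kit. Per the file headers, spot intensities were extracted from the scans with Agilent Feature Extraction 10.10.1.1 under its single-colour gene expression protocol. The deposited processed signal of each spot is an intensity on a linear scale, from which the extraction software had subtracted background and removed spatial trends within the array, without scaling between arrays. The deposited median spot and median local background intensity values are raw pixel brightness, and the deposited flags, 0 or 1, mark saturated, uneven or poorly detected spots. The deposited series table holds intensity values equal to the processed signal times 1 constant per array, to within 0.0373 on the log2 scale. It lists between 24939 and 35344 probes per array, and how the authors chose those probes and constants is not given in the sources used here.

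Each array had 45220 spots, of which 1417 were controls and were left out. Saturated spots numbered 0, and between 31 and 157 spots per array marked as uneven were set to missing. The 43603 distinct probes were matched to genes through a reference table of assembly WBcel235, used for names only because the array design cites an older build. A single gene was found for 34322 probes, 30980 by sequence name and 3342 by accession, which covered 19815 genes. The other 9281 probes had no match.

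Processed signals were put on the log2 scale, the array's 75th percentile was subtracted, and repeated spots of a probe were averaged. Probes were kept when they were well above background on all 3 arrays of at least 1 group. For each of the 5773 genes with several probes, the probe with the highest mean signal was used. This left 13472 genes. Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 12 arrays in the fit, and two-sided p-values adjusted by Benjamini and Hochberg over genes. A gene counted as changed at an adjusted p under 0.05, with no limit on fold. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

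For set tests, 35 gene lists were written before the data were examined, covering stress responses, metabolism, insulin signalling, germline, cuticle, immune and detoxification families, and markers of the main tissues. They were tested with limma's camera at a preset correlation of 0.01 between genes, and their p-values were adjusted over the lists. The same test with a correlation estimated from the data, and limma's fry, were run as alternatives. For these tests 278 missing values in 242 genes were replaced by group means. Counts of changed members are given after adjustment over all genes and after adjustment over the list alone.

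Genes named in the text were chosen by a rule fixed before the data were examined. Per comparison it took the 8 largest rises and the 8 largest falls among changed genes with a gene symbol whose groups did not overlap, up to 4 changed members of each list past the set test, and 11 genes fixed in advance. A microRNA locus picked by this rule in the comparison of 12 h with 3 h is left undescribed. Other genes named in the text were chosen after their values were seen.

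Each replicate letter or number stood for 1 slide of 4 arrays. Sets A and B were scanned on 1 day and set 1 on another, and each group always had the same position on its slide, so position and group cannot be separated. Deviations from group means were correlated across genes within each set. Arrays of the same set correlated at 0.444 to 0.891 in the N2 comparisons, and at 0.389, −0.387 and 0.133 for sets A, B and 1 in the daf-2 comparison, where the pairing rests on the shared slide alone. Counts with the replicate set as a fixed term (the replicate block) are therefore given beside every main count. Alternatives covered quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, median centring, the authors' series table (the authors' values, with fewer genes), other filters and probe rules, array weights, a variance prior with a trend, a random replicate block, a log2 limit of 1, fits of only the groups compared, and fits without single arrays or sets. Where a set was left out, each group kept 2 arrays. The fits without set A or B, a sperm gene covariate and the inclusion of probes without a gene were chosen after seeing the data, as were the tests of gene lists without any of the 3 sets. The normexp correction used the median spot intensity, because mean spot intensity was not analysed here.

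The method was tested on simulated data made from the real spread of these arrays, with 100 changed genes of each size among 13472. Each array was drawn independently, so the simulation lacked the correlation within replicate sets seen in the N2 arrays. Every comparison used the same spread and number of arrays, so the shares below differ between comparisons only by the random draw. At a log2 change of 1, the share recovered was 29% for 3 h against 15 °C, 31% for 12 h against 15 °C, 34% for 12 h against 3 h and 43% for daf-2 against N2. At a log2 change of 2 the shares were 79%, 80%, 85% and 77%. False calls numbered 5, 8, 1 and 9 genes, and 0 calls had the wrong sign. The number of arrays, 3 per group, limits the precision of every value.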

Results

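Gene expression in adult worms grown at 15 °C was compared before and after a shift to 25 °C, between 2 times after the shift, and between the wild-type strain N2 and daf-2(e1370), a mutant of the insulin-like receptor. The data were 12 arrays, 3 for each of 4 groups: N2 at 15 °C, N2 after 3 h at 25 °C, N2 after 12 h at 25 °C, and daf-2 after 12 h at 25 °C. Between 24259 and 26763 probes (55.6% to 61.4%) were well above background on the arrays of sets A and B, against 35242 to 37003 (80.8% to 84.9%) on those of set 1, which was scanned on another day. Within groups, arrays correlated at 0.92 to 0.983 across genes. The first principal component held 49.6% of the variance and separated daf-2 from N2; the second held 23.9% and separated set B from sets A and 1 among the N2 arrays. Signals are given as log2 values relative to the array's 75th percentile. The p-values measure the spread between these arrays, which can be technical, since the labels do not say that replicates were separate cultures and number sets A and 1 alike as replicate 1.

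Sperm genes differed between replicate sets of the same group. Over 50 sperm genes, among them the major sperm proteins that form the sperm's cytoskeleton, the N2 array of set B exceeded the mean of the sets A and 1 arrays by a median log2 difference of 4.42 at 15 °C, 2.57 after 3 h and 2.14 after 12 h. The daf-2 array of set B lay below its partners, with a median difference of −2.42. The set B difference was not confined to these 50 genes. At 15 °C the log2 excess was over 2 for 853 of 13422 genes outside the sperm lists (6.36%), against 47 of the 50. Those 853 can include sperm genes that are on neither list. Whether the difference reached beyond sperm genes was not tested.

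The first comparison addressed which transcripts differed after 3 h at 25 °C from those of worms kept at 15 °C. Small heat shock proteins, chaperones that hold unfolding proteins, were among the largest rises. The log2 signal of hsp-16.2 went from −4.14 ± 1.85 at 15 °C to 2.72 ± 0.85 after 3 h (SD, n = 3), a log2 rise of 6.86 ± 0.82 (SE; adjusted p = 0.0052), although it was well above background on only 2 of the 3 arrays at 15 °C. Its paralogs hsp-16.41, hsp-16.48 and hsp-16.1 rose 30.2-fold, 25.7-fold and 23.3-fold, and hsp-17 rose 6.27-fold. The cadmium-responsive gene cdr-4 rose 6.30-fold, and fat-6, a stearoyl-CoA desaturase that makes monounsaturated fatty acids, rose from 3.61 ± 0.18 to 4.82 ± 0.06 (SD, n = 3). Falls included cyp-35D1, a cytochrome P450 (log2 change −2.42 ± 0.30, SE), hrg-3 and hrg-4, genes of heme transport (−2.39 and −1.83), gsto-1, an omega-class glutathione transferase (−2.03), and endu-2, an endoribonuclease homolog (−1.67 ± 0.16).

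Of 20 measured cytosolic heat shock chaperones, 5 rose, 0 fell and 15 did not pass; adjusted over the list alone, 6 rose. This list was past the set test with an adjusted p of 7.6e-08, and kept its call at adjusted p = 0.0301 with an estimated correlation; with the replicate block added to that, adjusted p was 0.135. The inducible chaperone hsp-70 had a log2 change of 2.88 ± 0.71 (SE, n = 3) with adjusted p = 0.115, and did not pass. Some hsp-16 paralogs are similar in sequence, so that their probes can share signal, and probe sequences were not compared here.

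Genes of the endoplasmic reticulum unfolded protein response also shifted upward, with 5 of 19 rising and 0 falling; adjusted over the list alone, 8 rose. They included hsp-4, the reticulum's Hsp70 chaperone (1.72-fold), dnj-7, a co-chaperone (1.99-fold), pdi-6, a protein disulfide isomerase (1.69-fold), and ckb-2, a choline kinase (3.60-fold), whose other probe had a log2 change of −0.30; with median centring 2 of the 19 rose. The list had an adjusted p of 2.1e-08 in the set test, and adjusted p = 0.103 with an estimated correlation. Among UDP-glucuronosyltransferases, enzymes that conjugate lipophilic compounds, 6 of 59 rose, including ugt-66 (log2 3.37, well above background on 2 of 3 arrays at 15 °C), ugt-25 (1.75) and ugt-41 (1.72), and 0 fell; adjusted over the list alone, 15 rose and 2 fell. That list had adjusted p = 0.558 with an estimated correlation.

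Among the lists lower as a set, 4 of 101 C-type lectins fell, among them clec-7 (log2 −2.39, well above background on 2 of 3 arrays at 3 h) and clec-246 (−1.76), and 6 fell adjusted over the list alone, while 2 fell of the 84 with values in the authors' series table; the list had adjusted p = 0.796 with an estimated correlation. Of 44 glutathione S-transferases 3 fell, gsto-1, gst-35 and gst-41, while adjusted over the list alone 4 fell and 2 rose; the list had adjusted p = 0.871 with an estimated correlation. Early zygotic embryo genes (median log2 −0.59, 13 measured), antimicrobial peptides (−0.29, 21 measured) and cuticle collagens (−0.06 with a mean of 0.02, 132 measured) were lower with 0 changed members each, also adjusted over the list alone. Their values were adjusted p = 0.796, 0.836 and 0.907 with an estimated correlation. In sets A, B and 1 the medians were 0.05, −0.28 and −0.65 for antimicrobial peptides, 0.23, −0.18 and −0.49 for cuticle collagens and 0.02, −0.12 and −0.18 for C-type lectins.

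The remaining lists past the set test were higher with 0 changed members, also adjusted over the list alone. They were the major sperm proteins (median log2 1.14, 27 measured), other sperm genes (1.09, 23 measured), oxidative phosphorylation (0.14, 44 measured) and genes known to be lowered in daf-2 mutants (0.73, 6 measured). The first 3 had adjusted p = 0.871 with an estimated correlation, and the last had adjusted p = 0.796 with an estimated correlation. The median change of the major sperm proteins was 1.65, −0.08 and 1.88 in sets A, B and 1. In all, 12 of 35 lists passed, 7 higher and 5 lower. With the replicate block 9 passed; the cuticle collagens, C-type lectins and glutathione S-transferases then had adjusted p = 0.0519, 0.0727 and 0.0519.

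In limma, 137 of 13472 genes changed after 3 h, 95 higher and 42 lower, of which 105 changed at least 2-fold; 1242 genes had an unadjusted p under 0.05. All 137 had groups that did not overlap, which fixes the same direction in the 3 sets and adds no further support. Of the 137, 108 were well above background on all 6 arrays. Of the genes fixed in advance, daf-2, daf-16, sod-3, mtl-1, fat-5, fat-7 and vit-2 did not pass. The groups did not overlap for 1698 of 13472 genes, where chance gives 10% for exchangeable arrays, which arrays sharing a set are not. With the replicate block 319 genes changed, 222 higher and 97 lower, and 135 of the 137 kept their call. The count was 42, 52 and 59 without the N2 15 °C array of replicate A, B or 1, and 45, 60 and 79 without the corresponding 3 h array. It was 48 within the scan day of sets A and B, and 1 gene without set A or without set B (542 and 1256 at an unadjusted p under 0.05).

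**Figure D1:**
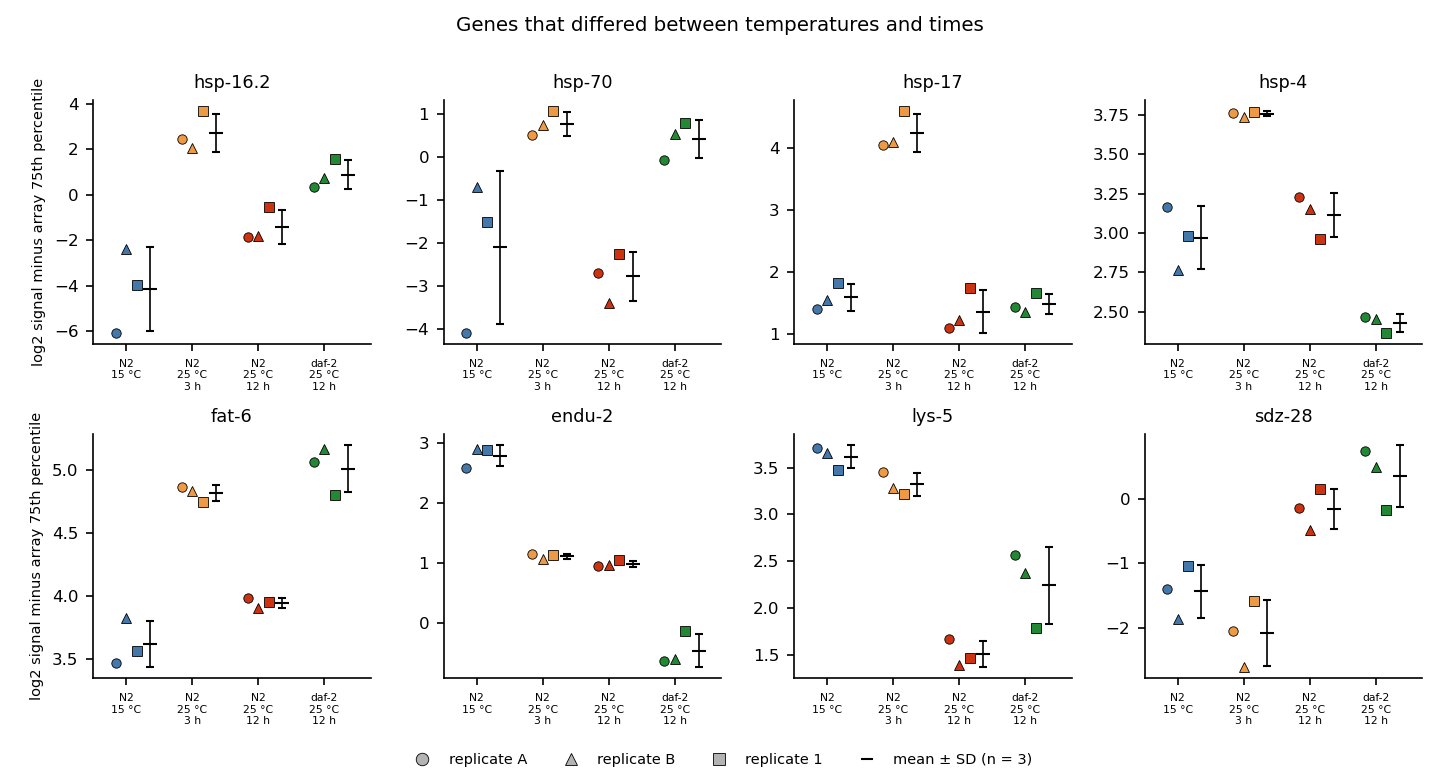
Log2 signal relative to the array's 75th percentile (vertical axis) for 8 genes on the 12 arrays, by group (horizontal axis). Points are arrays, with a shape for each replicate set, and bars are the mean ± SD of 3 arrays; hsp-17 averaged 4.25 after 3 h against 1.60 at 15 °C and 1.36 after 12 h in N2.

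The next comparison addressed the state of N2 after 12 h at 25 °C relative to 15 °C. The labels do not give the exact age of the worms. With a single N2 group at 15 °C, an effect of age cannot be told from that of temperature. Some genes for secreted enzymes and defence peptides fell, among them lysozymes, a cathepsin-like protease and a caenacin. The lysozyme lys-5 went from 3.61 ± 0.12 to 1.51 ± 0.14 (SD, n = 3), a log2 change of −2.11 ± 0.20 (SE; adjusted p = 0.00122), and lys-4 changed by −2.05 ± 0.25. The cathepsin B-like protease cpr-1 changed by −2.29 and the caenacin peptide cnc-2 by −2.17. Large rises were in scl-24, a secreted SCP-like protein (log2 4.23), sdz-6, an embryonic zygotic gene (4.22), ugt-66 (3.11), drd-50 (3.05), fbxc-34, an F-box gene (2.83), egas-3, an ion channel of the degenerin family (2.73), and clc-4, a claudin-like gene (2.71). Of these, scl-24, sdz-6, drd-50, fbxc-34, egas-3 and clc-4 were well above background on only 1 of 3 arrays at 15 °C, and ugt-66 on 2. Falls also reached dhs-26, a short-chain dehydrogenase (−2.84), tre-5, a trehalase (−2.56), col-40, a cuticle collagen (−2.3), and gsto-1 (−2.13); after 12 h, tre-5 and col-40 were well above background on 1 of 3 arrays and dhs-26 on 2.

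Of 33 lysozymes and saposins, 4 fell, namely lys-5, lys-4, ilys-2 (log2 −1.38) and spp-25 (−1.12), and 0 rose; adjusted over the list alone, 10 fell. The list had an adjusted p of 2.2e-06 in the set test, and adjusted p = 0.773 with an estimated correlation. Antimicrobial peptides had a median log2 change of −0.67, with 1 of 21 falling (cnc-2); adjusted over the list alone, 6 fell and 1 rose. They too had adjusted p = 0.773 with an estimated correlation. Among 16 intestine markers 2 fell, cpr-1 and the aspartyl protease asp-3 (−0.79), also adjusted over the list alone, with adjusted p = 0.773 with an estimated correlation. Ribosomal proteins (median −0.16, 63 measured) and proteasome subunits (−0.13, 32 measured) were slightly lower with 0 changed members, also adjusted over the list alone, and had adjusted p = 0.791 and 0.899 with an estimated correlation; with quantile normalization the ribosomal median was −0.01 and the proteasome median −0.09. The proteasome median was −0.18, 0.11 and −0.30 in sets A, B and 1.

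The lists that were higher at 12 h had weak calls. Among UDP-glucuronosyltransferases 6 of 59 rose, including ugt-3 (log2 2.37, well above background on only 1 of 3 arrays at 15 °C) and ugt-43 (2.03), and 3 fell, including ugt-31 (−1.59); adjusted over the list alone, 16 rose and 6 fell. Early zygotic embryo genes had a median log2 change of 0.51, with 0 of 13 past and 2 higher adjusted over the list alone. Of 46 histones 1 rose (his-11, 2.07-fold), also adjusted over the list alone. Of 23 other sperm genes 1 rose, the kinase gene spe-6 (log2 1.14), also adjusted over the list alone; the list's median change was 2.68, −0.42 and 0.91 in sets A, B and 1. All of these 4 lists had adjusted p = 0.899 with an estimated correlation. In all 9 lists passed, 4 higher and 5 lower, and 0 kept the call with an estimated correlation; with the replicate block 8 passed, and other sperm genes then had adjusted p = 0.062.

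In limma, 360 genes changed after 12 h, 255 higher and 105 lower, of which 263 changed at least 2-fold. An unadjusted p under 0.05 was found for 2110 genes, and 281 of the 360 were well above background on all 6 arrays. For all 360 the groups did not overlap, which fixes the same direction in every set and adds no further support. The same direction was counted in all 3 sets for 358, which leaves out genes with a missing spot. The groups did not overlap for 20.7% of genes, where chance gives 10% for exchangeable arrays, which arrays sharing a set are not. With the replicate block 1024 genes changed, 689 higher and 335 lower, including all 360. The count was 137 and 198 without the N2 15 °C array of replicate A or B, and 133, 128 and 213 without the 12 h array of replicate A, B or 1. It was 283 within the scan day of sets A and B, and 0 without set A or without set B (1014 and 1841 at an unadjusted p under 0.05). The small heat shock gene hsp-16.2 (log2 2.73 ± 0.82, adjusted p = 0.123) and the desaturase fat-7 (−2.01 ± 0.85, adjusted p = 0.28) did not pass; fat-7 had adjusted p = 0.0321 with the replicate block and 0.0321 to 0.791 over its alternatives.

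A direct comparison of 12 h with 3 h at 25 °C addressed which early differences were gone later. Heat shock genes were lower at 12 h: hsp-16.2 changed by −4.13 ± 0.82 (SE, n = 3; adjusted p = 0.0375), hsp-70 by −3.55 ± 0.71, hsp-17 by −2.88 ± 0.22, hsp-16.48 by −2.2 and hsp-16.1 by −2.11. The desaturase fat-6 changed by −0.87 ± 0.15, cdr-4 by −2.80, and the reticulum chaperone hsp-4 by −0.64 ± 0.14. Higher at 12 h were zip-8, a bZIP factor (log2 2.79), the homeodomain gene unc-39 (2.52), the lectins clec-196 and clec-266 (2.33 and 2.25), and the F-box genes fbxc-34, fbxb-116 and fbxb-111 (2.48, 2.40 and 2.22). At 3 h, unc-39, fbxc-34 and fbxb-111 were well above background on only 1 of 3 arrays, and fbxb-116 on 2.

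Of 20 heat shock chaperones 5 fell and 0 rose, and 10 fell adjusted over the list alone; the list had an adjusted p of 2.8e-09 in the set test and adjusted p = 0.0173 with an estimated correlation, or 0.108 with the replicate block as well. Of 19 unfolded protein response genes of the endoplasmic reticulum 2 fell, hsp-4 and ckb-2 (log2 −1.25); adjusted over the list alone, 5 fell and 1 rose, and the list had adjusted p = 0.319 with an estimated correlation. Early zygotic embryo genes, first transcribed in the embryo, were higher, with 4 of 13 rising: sdz-28 (1.92 ± 0.33, SE), sdz-38 (1.56), vet-6 (1.47) and hlh-1, the MyoD homolog (1.29). Adjusted over the list alone, 10 rose, and the list's median change was 1.02, 1.02 and 0.99 in sets A, B and 1; it had adjusted p = 0.319 with an estimated correlation.

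Lysozymes and saposins were lower at 12 h than at 3 h, with 2 of 33 falling, lys-5 (log2 −1.81) and lys-4 (−1.77), and 3 falling adjusted over the list alone; the median difference was −0.54, −0.56 and 0.10 in sets A, B and 1. They had adjusted p = 0.721 with an estimated correlation. Antimicrobial peptides, ribosomal proteins and proteasome subunits were lower with 0 changed members, also adjusted over the list alone. Their medians were −0.30, −0.22 and −0.18 (−0.32, −0.02 and −0.10 with quantile normalization), with adjusted p = 0.975, 0.319 and 0.975 with an estimated correlation. For antimicrobial peptides the median was −0.61, −0.52 and 0.20 in sets A, B and 1. In all 7 lists passed, 1 higher and 6 lower; 8 passed with the replicate block, where histones also did (adjusted p = 0.0148), and 11 within the scan day of sets A and B, a test chosen after seeing the data.

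In limma, 285 genes differed between 12 h and 3 h, 209 higher and 76 lower, of which 231 differed at least 2-fold; 1645 had an unadjusted p under 0.05. All 285 had groups that did not overlap, which fixes the same direction in the 3 sets and adds no further support. Of the 285, 224 were well above background on all 6 arrays. The groups did not overlap for 17.4% of genes, where chance gives 10% for exchangeable arrays, which arrays sharing a set are not. With the replicate block 727 genes differed, 534 higher and 193 lower, including all 285; fat-7 (log2 −2.17 ± 0.85, adjusted p = 0.297) then had adjusted p = 0.0291, against 0.0161 to 0.951 over its alternatives. The count was 31 and 41 without the 3 h array of replicate A or B, and 38, 34 and 54 without the 12 h array of replicate A, B or 1. It was 309 within the scan day of sets A and B, and 0 without set A or without set B (860 and 1158 at an unadjusted p under 0.05).

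The genes changed at 3 h and at 12 h overlapped: 51 were past the threshold in the same direction at both times, 35 higher and 16 lower, and 1 in opposite directions. Independent lists would share 1.80 higher and 0.327 lower genes. Both comparisons use the same arrays at 15 °C. Simulated data with no real effect gave 0.05 shared genes. Almost no gene passes without an effect, so this cannot show what the shared arrays add. Across genes, which are not independent replicates, the 2 sets of changes correlated at 0.547, against 0.499 in simulated data with the shared arrays and no effect. Those data were drawn independently for each array, without the correlation within replicate sets, so 0.499 is not an exact reference. The shared genes included hsp-16.41 (log2 4.92 at 3 h and 2.57 at 12 h), ugt-66 (3.37 and 3.11), cyp-35D1 (−2.42 and −2.11), the heme transport gene hrg-3 (−2.39 and −2), gsto-1 (−2.03 and −2.13) and endu-2 (−1.67 and −1.80). There were 155 shared genes with the replicate block.

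The last comparison set daf-2 against N2, both after 12 h at 25 °C. Some genes known to be driven by DAF-16, the transcription factor released when insulin signalling is low, were higher in daf-2. The metallothionein mtl-1 went from −1.59 ± 1.5 in N2 to 5.09 ± 0.23 in daf-2 (SD, n = 3), a log2 difference of 6.69 ± 0.88 (SE; adjusted p = 0.00064). The ferritin gene ftn-1 rose by 5.70 ± 0.36, and sod-3, a mitochondrial superoxide dismutase, by 3.26 ± 0.24. The inducible chaperone hsp-70 rose by 3.20 ± 0.71, while the reticulum chaperone hsp-4 changed by −0.69 ± 0.14. Large rises were in scl-20, a secreted SCP-like protein (9.12 ± 0.46), and col-50, a cuticle collagen (8.51 ± 0.45), whose other probe gave 2.65. Further rises were in col-183 (7.65), icmt-1 (6.93), lpr-4, a lipocalin-related gene (6.03), and dsl-6, a Delta-like ligand (5.91). In N2 at 12 h, scl-20, col-50, col-183, lpr-4 and dsl-6 were well above background on only 1 of 3 arrays. The gene cdr-3 also rose, but it was well above background on 0 of these N2 arrays, so the size of its rise is not given. Large falls were in drd-50 (−4.02), the acyltransferase gene oac-20 (−3.81), fbxa-72 (−3.74), dod-22 (−3.47), herc-1 (−3.43), the aquaporin aqp-8 (−3.30), pugs-8 (−3.17) and col-43 (−3.04); in daf-2, drd-50, oac-20 and herc-1 were well above background on 1 of 3 arrays. The daf-2 and daf-16 transcripts themselves differed by 0.14 ± 0.51 and −0.05 ± 0.13, with adjusted p = 0.85 and 0.773.

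Of 19 genes known as raised by DAF-16, 13 rose and 0 fell, among them hsp-12.3, a small heat shock protein (log2 4.26), and dod-3 (4.03); adjusted over the list alone, 13 rose and 1 fell. The list's median change was 1.64, 1.71 and 1.38 in sets A, B and 1, and it had adjusted p = 0.201 with an estimated correlation. Of 6 genes known to be lowered in daf-2 mutants, 5 fell, including dod-22, dod-17 (−3.02) and the insulin-like gene ins-7 (−1.77), and 6 fell adjusted over the list alone. Among 30 insulin-like peptides 13 rose, led by ins-10 (4.26), ins-2 (4.23) and ins-35 (3.25), and ins-7 fell; adjusted over the list alone, 17 rose and 1 fell. In N2, ins-2 was well above background on only 1 of 3 arrays, and ins-10 on 2. Both of these lists had adjusted p = 0.23 with an estimated correlation.

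Some lipid and sugar metabolism genes rose in daf-2. In lipid breakdown 7 of 27 rose, including lipl-4, a lysosomal lipase (log2 4.93), and the carnitine palmitoyltransferase genes cpt-3 (3.53) and cpt-4 (3.01), and 0 fell, the same counts as adjusted over the list alone; in N2, lipl-4 was well above background on only 1 of 3 arrays, and cpt-4 on 2. The list had adjusted p = 0.276 with an estimated correlation. In fatty acid desaturation and elongation 5 of 20 rose, including fat-5, a palmitoyl-CoA desaturase (2.57 ± 0.30, SE), and fat-6 (1.07 ± 0.15), also adjusted over the list alone, and 3 rose with median centring; adjusted p = 0.51 with an estimated correlation. The desaturase fat-7 (−0.74 ± 0.85, adjusted p = 0.526) and the yolk protein gene vit-2 (−0.37 ± 0.38, adjusted p = 0.487) did not pass. In trehalose, glycerol and glyoxylate metabolism 3 of 6 rose, namely icl-1, the glyoxylate enzyme (4.28-fold), and the trehalose synthases tps-1 (2.63-fold) and tps-2 (2.58-fold), also adjusted over the list alone; adjusted p = 0.23 with an estimated correlation.

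Some immune and detoxification families shifted upward in daf-2, while C-type lectins (15 rose, 23 fell), antimicrobial peptides (4 rose, 2 fell) and glutathione S-transferases (9 rose, 6 fell) were not past the set test. Of 33 lysozymes and saposins 13 rose, including spp-20 (log2 5.65), spp-13 (4.35) and spp-12 (4.30), and 0 fell; adjusted over the list alone, 17 rose and 2 fell, with adjusted p = 0.39 with an estimated correlation. Of 21 genes of the intracellular pathogen response 13 rose, including pals-39 (4.41), pals-26 (4.34) and pals-14 (4.31), and 1 fell; adjusted over the list alone, 14 rose and 1 fell, with adjusted p = 0.23 with an estimated correlation. Of 56 cytochrome P450s 25 rose, including cyp-14A4 (4.26) and cyp-35B1 (4.20), and 2 fell; adjusted over the list alone, 28 rose and 2 fell, with adjusted p = 0.23 with an estimated correlation. Of 59 UDP-glucuronosyltransferases 18 rose, including ugt-57 (3.35) and ugt-40 (2.29), and 10 fell; adjusted over the list alone, 22 rose and 11 fell, with adjusted p = 0.539 with an estimated correlation and a median of 0.37, 0.74 and −0.03 in sets A, B and 1. Of the genes with values in the authors' series table, which covers fewer, 6 of 14 in the intracellular pathogen response and 16 of 45 cytochrome P450s rose. In N2, spp-20, spp-12, pals-39, pals-26, pals-14, cyp-14A4, cyp-35B1, ugt-57 and ugt-40 were well above background on only 1 of 3 arrays and spp-13 on 2, so that their log2 rises were measured against background.

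Some cuticle and nerve genes rose in daf-2. Of 15 molting cycle genes, which rebuild the cuticle between larval stages, 8 rose and 0 fell, including mlt-11 (log2 4.67), ptr-4 (4.15), wrt-10 (3.65) and fbn-1 (3.55), also adjusted over the list alone; adjusted p = 0.448 with an estimated correlation. Of 14 epidermis markers 3 rose, the secreted wrt-2 (4.88), the collagen dpy-7 (4.87) and the junction gene ajm-1 (1.26), and 5 rose adjusted over the list alone; adjusted p = 0.395 with an estimated correlation. Of 16 thermosensory and cold tolerance neuron genes 5 rose, including the homeodomain gene ttx-1 (2.18), the channel subunit tax-2 (1.37) and the neuronal thioredoxin trx-1 (2.70), and 7 rose adjusted over the list alone; adjusted p = 0.23 with an estimated correlation, and 0.0694 with the replicate block. In N2, mlt-11 and wrt-10 were well above background on all 3 arrays, while fbn-1, wrt-2, dpy-7, ttx-1, tax-2 and trx-1 were so on only 1 and ptr-4 on 2. Of the genes with values in the authors' series table, 5 of 12 molting and 2 of 12 thermosensory genes rose.

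Some germline genes fell in daf-2. Of 20 genes of germline proliferation and meiosis 9 fell and 0 rose, including the P granule gene pgl-1 (log2 −0.89) and the meiotic cohesin rec-8 (−0.82); adjusted over the list alone, 12 fell, with adjusted p = 0.39 with an estimated correlation. Of 28 oocyte and maternal genes 7 fell, including gld-1, a translational repressor (−1.09), and the yolk receptor rme-2 (−0.81), and the caveolin cav-1 rose (1.49), also adjusted over the list alone; adjusted p = 0.505 with an estimated correlation. Of 23 other sperm genes 3 fell, spe-41 (−1.62), spe-6 (−0.97) and spe-44 (−0.68), and 1 fell adjusted over the list alone; adjusted p = 0.711 with an estimated correlation. The 27 major sperm proteins were lower as a set with 0 changed members, also adjusted over the list alone, and adjusted p = 0.723 with an estimated correlation. Their median difference was −1.43, −5.36 and 0.29 in sets A, B and 1, and that of the other sperm genes −1.30, −4.47 and 0.33. With quantile normalization 4 germline, 2 oocyte and 3 other sperm genes fell, and with the authors' values, for the same numbers of genes, 5, 4 and 1.

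Some ribosomal, proteasome and respiration genes fell in daf-2 by smaller amounts. Of 63 ribosomal proteins 12 fell, including rpl-12 (log2 −0.81) and rps-28 (−0.78), and 11 fell adjusted over the list alone; adjusted p = 0.23 with an estimated correlation. Of 32 proteasome subunits 9 fell, including pbs-4 (−0.67) and pbs-6 (−0.65), and 19 fell adjusted over the list alone; adjusted p = 0.51 with an estimated correlation. Of 44 oxidative phosphorylation genes 5 fell, including cox-17 (−0.70) and the ATP synthase gene atp-2 (−0.64), and 2 fell adjusted over the list alone; adjusted p = 0.51 with an estimated correlation. With quantile normalization, limma called 0 ribosomal proteins (3 lower at an unadjusted p under 0.05), 7 proteasome subunits and 2 oxidative phosphorylation genes lower, and with the authors' values 5, 9 and 4. The median of all genes was −0.14 in this comparison and between −0.24 and −0.06 under other scalings. Relative to it the medians were −0.23 for ribosomal proteins, which turned to 0.03 with quantile normalization and 0.01 with normexp and quantile normalization, −0.42 for proteasome subunits and −0.24 for oxidative phosphorylation.

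**Figure D2:**
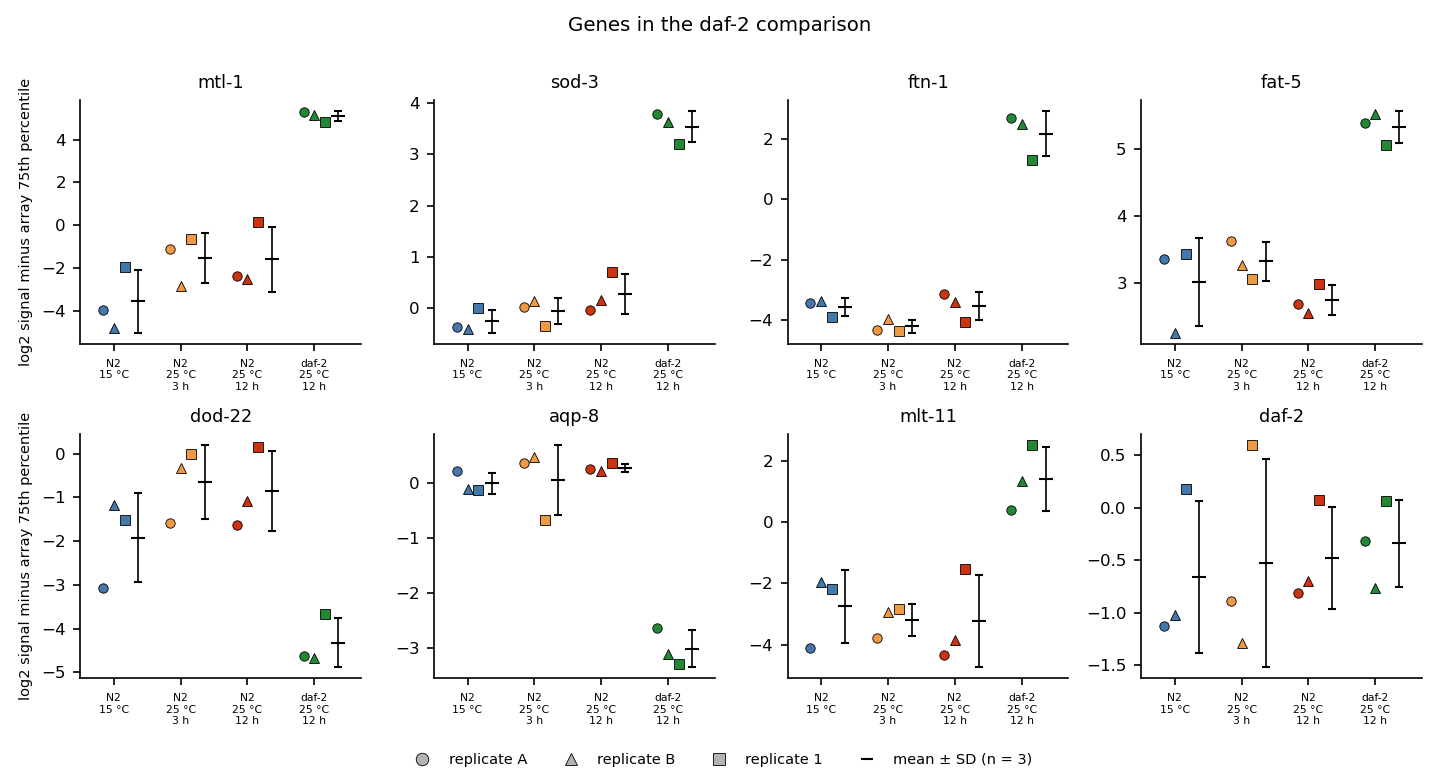
Log2 signal relative to the array's 75th percentile (vertical axis) for 8 genes on the 12 arrays, by group (horizontal axis). Points are arrays, with a shape for each replicate set, and bars are the mean ± SD of 3 arrays; sod-3 averaged 3.54 in daf-2 against 0.28 in N2 after 12 h at 25 °C.

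In limma, 2952 genes differed between daf-2 and N2, 1952 higher and 1000 lower, of which 1827 differed at least 2-fold. An unadjusted p under 0.05 was found for 4914 genes, and 2356 of the 2952 were well above background on all 6 arrays. The same direction held in all 3 sets for 2934 of the 2952. That adds little, since for 2928 the groups did not overlap, which fixes the direction where no spot was missing. The groups did not overlap for 43.1% of genes, where chance gives 10% for exchangeable arrays, which arrays sharing a set are not. With the replicate block 5027 genes differed, 2690 higher and 2337 lower, and 2951 of the 2952 kept their call; hsp-16.2 (4.91-fold higher, adjusted p = 0.0723) then had adjusted p = 0.0338, against 0.00476 to 0.207 over its alternatives. The count was 1613 and 1728 without the N2 array of replicate A or B, 1959 without the daf-2 array of replicate B, 2746 within the scan day of sets A and B, and 849 and 789 without set A or without set B. Of the 35 lists 20 passed, 12 higher and 8 lower, 0 of them with an estimated correlation and 20 with the replicate block, where the mitochondrial chaperones and proteases passed in place of the thermosensory list (adjusted p = 0.0362).

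The 360 genes that changed after 12 h at 25 °C in N2 were then followed in daf-2. Among them 69 differed between the strains in the direction opposite to the N2 change, 43 higher and 26 lower in N2 after 12 h, while 92 differed in the same direction, 76 higher and 16 lower. Independent lists would share 18.9 and 15.2 opposed genes, and 36.9 and 7.79 in the same direction. Simulated data without effects, which keep the shared N2 arrays, gave 0 in either direction. Almost no gene passes without an effect, so this cannot show what the shared arrays add to the overlaps. Opposed genes included sdz-6 (log2 4.22 in N2 at 12 h against 15 °C, −2.99 in daf-2 against N2), drd-50 (3.05 and −4.02), dhs-26 (−2.84 and 2.74), cpr-1 (−2.29 and 1.88) and lys-5 (−2.11 and 0.74). Opposed does not mean reversed from 15 °C. On all daf-2 arrays sdz-6 stayed above, and lys-5 below, every N2 array at 15 °C. The daf-2 and N2 15 °C arrays overlapped for drd-50, dhs-26 and cpr-1. Across genes the 2 sets of changes correlated at −0.0377 against −0.497 in simulation, where the arrays of a replicate set were drawn independently. There were 195 opposed genes with the replicate block and 38 with a log2 limit of 1. A daf-2 group at 15 °C was not analysed here, so whether the strains respond differently to temperature was not tested.

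**Figure D3:**
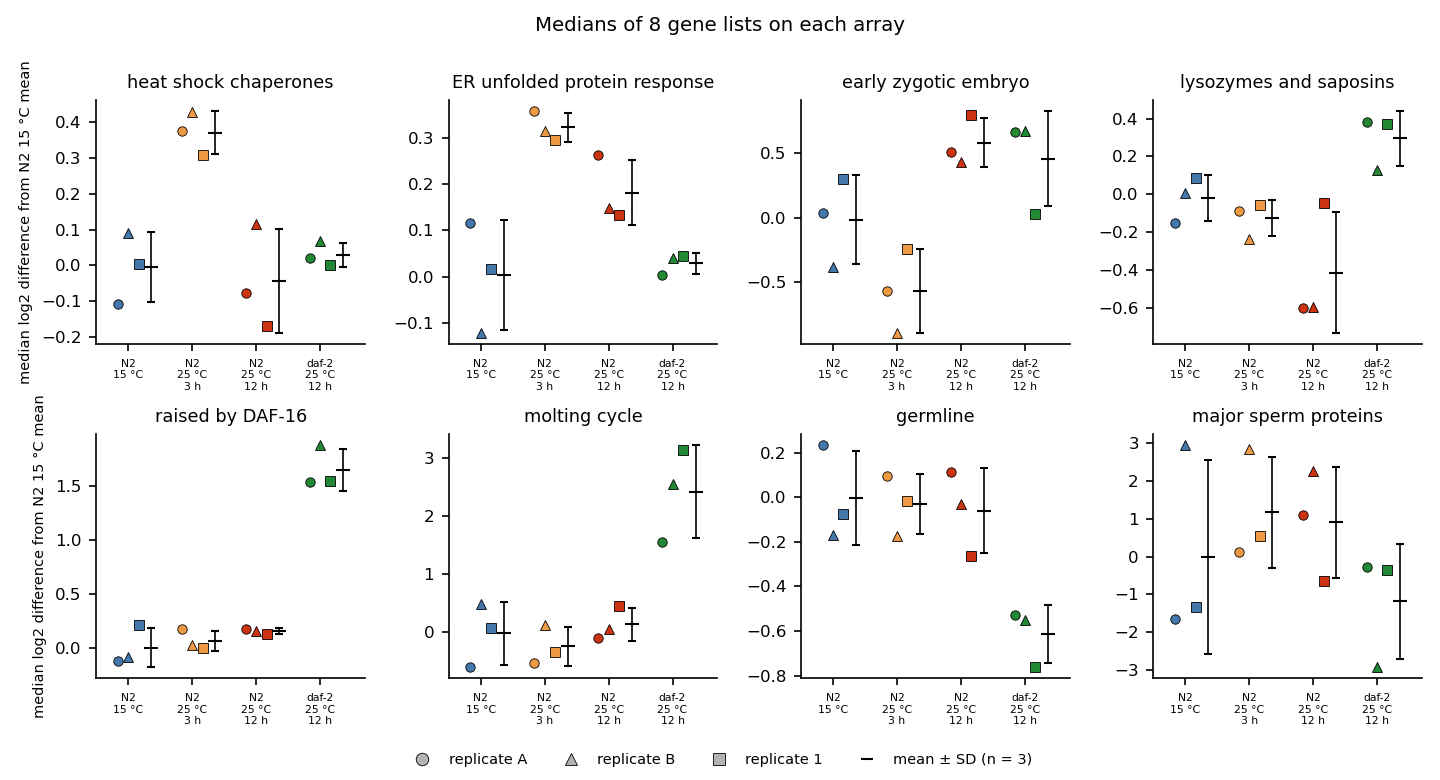
Median over the members of 8 gene lists of the log2 difference from the mean of N2 at 15 °C (vertical axis), by group (horizontal axis). Points are arrays, with a shape for each replicate set, and bars are the mean ± SD of 3 arrays; genes raised by DAF-16 averaged 1.65 ± 0.19 in daf-2 against 0.16 ± 0.03 in N2 at 12 h, and major sperm proteins were highest on the set B array of each N2 group.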

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

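The tests of slide effects, of sperm protein copies, of germline share, of stage and of scaling in the paragraphs that follow were chosen after the results were seen; the tests of dim probes, bright probes and other splits were fixed earlier.

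Several genes differed between the times at 25 °C when 12 h was tested directly against 3 h with limma. Lower at 12 h were genes that had risen at 3 h, with a log2 difference of −4.13 for hsp-16.2, −2.88 for hsp-17, −2.80 for cdr-4, −2.2 for hsp-16.48, −2.11 for hsp-16.1, −1.37 for ugt-36, −1.25 for ckb-2, −0.87 for fat-6 and −0.64 for hsp-4. The difference was −3.55 for hsp-70, which was not past the threshold against 15 °C at 3 h or 12 h. Of these genes, hsp-16.48 (log2 2.48) and hsp-16.1 (2.43) were also past the threshold at 12 h against 15 °C. The difference was 2.18 for sdz-6, past the threshold at both times. Among genes past the threshold at 12 h and not at 3 h, fbxc-34 differed by 2.48 and ugt-3 by 1.45, while dhs-26 differed by −2.55, cpr-1 by −1.97, lys-5 by −1.81, lys-4 by −1.77 and asp-3 by −0.80.

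Past the set test between the times were 7 gene lists. Of these 1, the heat shock chaperones, kept the call with an estimated correlation (adjusted p = 0.0173), and 0 did with the replicate block as well. With the estimated correlation alone, the other 6 had adjusted p from 0.319 to 0.975. The median log2 difference between 12 h and 3 h was −0.47 for heat shock chaperones, −0.22 for the endoplasmic reticulum unfolded protein response, 0.97 for early zygotic embryo genes, −0.30 for antimicrobial peptides, −0.44 for lysozymes and saposins, −0.22 for ribosomal proteins (−0.02 with quantile normalization) and −0.18 for proteasome subunits.

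Probes without a gene in the reference table were outside the comparisons of the report, and some gave signals past the same threshold. Of 2285 such transcripts, 11 changed at 3 h, 32 at 12 h, 14 between 12 h and 3 h, and 321 between daf-2 and N2.

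Other splits of the 6 arrays of each comparison into 3 and 3 gave as many changed genes in 1 of 10 splits, the real grouping itself, in each of the 4 comparisons. The real counts were 137, 360, 285 and 2952, and the highest among the other splits were 0, 0, 1 and 0. With 10 splits no share under 0.1 is possible. Arrays of a set share a slide, and only 4 of the 10 splits, the real one among them, part all 3 same-set pairs. With that pairing kept, the smallest possible share is 1 of 4.

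Sperm genes were higher on the N2 arrays of set B than on those of sets A and 1. Background on dim probes was excluded as the cause, since sperm genes brighter than the 75th percentile had the same excess at 15 °C (4.41). Signal shared between near-identical major sperm protein copies was also excluded, since sperm genes outside that family had an excess of 4.43. A slide or hybridization effect stays open, because the daf-2 array on the same slide went the other way (−2.42) but is a single array. No biological explanation was tested, since the labels give neither the age of the worms nor the time since they became adult.

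In daf-2 the molting list was past the set test as higher and the germline, oocyte and sperm lists as lower, none of them with an estimated correlation (adjusted p = 0.39 to 0.723), and the sperm lists were higher in set 1. A lower share of germline with no other change should have raised neuron, body wall muscle, intestine and epidermis markers alike. Epidermis exceeded intestine by a log2 difference of 0.702 ± 0.138 (SD, n = 3 sets). The epidermis list is not separate from the pattern, since nhr-23 is also on the molting list and dpy-7 is a cuticle collagen. The median difference in sets A, B and 1 was 0.16, 0.36 and 0.26 for neuron and −0.38, −0.21 and −0.40 for intestine markers. For body wall muscle markers it was −0.01, −0.63 and −0.06. Neuron markers rose and intestine markers fell in every set, but neither list was past the set test. Random gene lists as bright as the ribosomal, proteasome and oxidative phosphorylation lists also fell, with medians of −0.29, −0.28 and −0.27. Intestine markers were not compared with genes of their own brightness. Their fall therefore cannot decide whether a lower germline share was the whole cause. A difference in developmental stage between the strains at harvest stays open. In sets A, B and 1 the median difference was 2.09, 2.40 and 1.79 for molting genes. It was 1.64, 1.71 and 1.38 for genes raised by DAF-16, the same order. A shared order was chosen as a sign of a stage difference only after the results were seen, and 3 sets cannot decide. A response to low insulin signalling would also raise the genes raised by DAF-16.

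The ribosomal, proteasome and oxidative phosphorylation lists were past the set test as lower in daf-2, with only a part of their members changed. With an estimated correlation, 0 of the lists in this comparison passed. Relative to the median of all genes, quantile normalization left a median of 0.0254 for ribosomal proteins, which is what an effect of scaling would give, −0.31 for proteasome subunits, which argues against scaling, and −0.11 for oxidative phosphorylation, which leaves it open. Against 10000 random lists of the same brightness, the oxidative phosphorylation list lay at percentile 2.65, where lower signal of bright probes can still account for it. The percentile was 0.36 for ribosomal proteins. Their median of −0.37 was under the preset lower limit of the random lists, −0.35, but by less than those lists' SD of 0.0379. The random lists themselves had a median of −0.29, which leaves this open. For proteasome subunits the percentile was 0, which argues against it only as far as these random lists go. Their genes were drawn at random, without the correlation between members of a real list, so their spread can be too narrow. Of the 3 lists, only the lower proteasome genes were left without a technical explanation among those tested.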

How the results depend on the processing

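The fits without set A or without set B, the covariate fit, the fit with unnamed probes and the list tests without set 1 were chosen after seeing the data, as were the tests on them.

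The numbers of changed genes kept within 1.5 times of the main count under quantile normalization, normexp and quantile normalization, median centring, the authors' series table, probes well above background on all 12 arrays, the mean of a gene's probes and another variance prior. Where they moved further, the cause was not tested, except that fits without arrays have fewer samples. In the order 3 h against 15 °C, 12 h against 15 °C, 12 h against 3 h and daf-2 against N2, the main counts were 137, 360, 285 and 2952. They became 319, 1024, 727 and 5027 with the replicate block and 388, 1124, 836 and 4958 with a random replicate block. The first 3 became 48, 162 and 47 with no filter on dim probes, and 0, 93 and 10 in limma with only the 2 groups compared, where 1066 genes at 3 h had an unadjusted p under 0.05. Array weights gave 804, 843 and 6521 for the last 3, the sperm gene covariate 583 and 462 for the 2 comparisons of 12 h within N2, and a log2 limit of at least 1 left 1827 for daf-2. Leaving out arrays or sets gave 1 to 79, 0 to 283, 0 to 309 and 789 to 3141. A block for slide was not run, because slide and replicate set were the same.

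Gene lists past the set test, 12, 9, 7 and 20 in the same order, became 1, 0, 1 and 0 with an estimated correlation, and 2, 0 and 4 with fry for the first 3 comparisons. Leaving out arrays or sets gave 5 to 14, 7 to 11, 6 to 11 and 18 to 21 lists, while the replicate block changed the list calls named in the report and no other. The 51 genes shared between 3 h and 12 h became 16 with no filter and 155 with the replicate block. The 69 opposed genes became 26 with no filter, 195 with the replicate block and 38 with a log2 limit of at least 1.

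Over the named genes and lists, 4303 alternative values kept their side of the threshold, 1073 no longer passed, 15 newly passed and 0 reversed. A list that turned direction without passing counted among those no longer passing. A gene past neither there nor in the main fit counted as kept, whatever its sign. Named genes that passed kept their call under every alternative in 40 of 90 cases for daf-2. The counts were 0 of 27 at 3 h, 0 of 26 at 12 h and 0 of 25 for 12 h against 3 h. In each of these N2 comparisons an alternative called 0 genes in all, so these counts were fixed at 0 and do not measure stability. Signal over background limits the detection of weakly expressed genes: between 55.6% and 61.4% of probes were well above background on the arrays of sets A and B, and 80.8% to 84.9% on those of set 1.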

Other observations

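The tests of gene families by name in this part were chosen after the results were seen, over 161 families per comparison.

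F-box genes of the fbxb family, which encode adaptors for protein degradation, were higher at 12 h than at 3 h at 25 °C in N2. Of 94 members 17 rose and 0 fell, with a median log2 change of 1.44, among them fbxb-116 (2.40), fbxb-111 (2.22) and fbxb-48 (2.09). Of 40 fbxc genes 8 rose and 2 fell. Of 27 sdz genes, named for expression in the early embryo under the SKN-1 factor, 8 rose, including sdz-6 (2.18) and sdz-25 (1.93), and of 45 homeobox ceh genes 4 rose, including ceh-16 (2.04), ceh-27 (1.48) and ceh-43 (1.47), with a median of 0.18. At 3 h, fbxb-111, fbxb-48 and ceh-27 were well above background on only 1 of 3 arrays, and fbxb-116 and ceh-16 on 2. The fbxb family had an adjusted p of 1.8e-41 in the set test, and adjusted p = 0.779 with an estimated correlation, as did sdz and ceh, while fbxc had 0.979.

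In daf-2 against N2, 14 of 19 cutl genes, which encode cuticlin-like proteins, rose, led by cutl-2 (log2 3.54) and cutl-28 (3.48, well above background on only 1 of 3 N2 arrays). Of 30 carboxylesterases 17 rose and 2 fell, including cest-1.1 (5.26), and of 49 transthyretin-related genes 17 rose and 1 fell, including ttr-23 (4.21). Of 10 dyf genes, needed for the uptake of dye by sensory neurons, 7 rose, with a median of 1.92. Subunits of the vacuolar proton pump were lower, with 8 of 20 falling, including vha-6 (−1.41) and vha-12 (−1), as were mitochondrial ribosomal proteins, with 7 of 41 mrpl and 5 of 29 mrps genes falling, including mrps-15 (−1.17). All of these families had adjusted p = 0.81 with an estimated correlation.

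Cuticle collagens, C-type lectins and glutathione S-transferases had changed members in daf-2 in both directions and were not past the set test. Among 132 collagens 12 rose, including dpy-2 (4.24), dpy-17 (4.16) and sqt-3 (3.58), and 7 fell. Among the lectins 15 rose and 23 fell, and among the transferases 9 rose and 6 fell.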
